A study of Homo sapiens with 18 samples.

How the data were processed

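RNA was extracted with TRIzol from HepG2 and LX2 cells and libraries were made with a VAHTS Universal V6 kit, per the labels' protocols. The 18 libraries form 6 groups of 3: each of the 2 lines with 30 µM aristolochic acid I (AA), 30 µM aristolactam AII (AL) or DMSO, for 48 h in 12 well plates. The authors deposited a table of 34415 genes with whole-number counts per gene and library and with FPKM values beside them. The submitters' processing notes name HISAT2, HTSeq and hg19. Their versions and roles, the gene annotation and the use of strand are not given in the sources used here. The deposited FPKM values were checked against the counts: for 16459 of 16459 genes with enough counts (100%) they imply 1 gene length in every library to within 1e-6, and those of 17071 genes (100%) are whole numbers within 0.001. These implied lengths served as exonic lengths.

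Table columns are coded by line and treatment. The labels spell AA for aristolochic acid I, and the columns coded AAA were taken as AL because it is the only group left; AAA could also abbreviate another name of the acid, and this was not settled from the values. No column was left unmapped. Total counts per library ran from 37697210 to 40873144 in HepG2 and from 39609564 to 41142451 in LX2. Counts of all 18 pairs of replicates differed by more than sampling noise (chi-square per degree of freedom 4.70 to 14.1), so no library was treated as a copy of another. TMM factors were 1.07 to 1.09 in the AA libraries of HepG2 and 0.945 to 0.980 in the other HepG2 libraries.

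Counts as deposited were tested with edgeR 4.0.16 (glmQLFit with robust=TRUE, glmQLFTest, two-sided) in R 4.3.3, after TMM normalization and filterByExpr by group, in 1 fit over the 9 libraries of a line with no replicate block. The difference of responses between lines was the interaction contrast in a fit over all 18 libraries. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. SE and 95% intervals come from the same fits, and CPM values use TMM-scaled library sizes of the same fit. A fold against a group with 0 counts is a lower bound from a floor of 3 counts over the group; with 1 to 3 counts the ratio is given with its 95% counting interval. The 39 gene lists, with 1106 symbols of which 1100 matched the table, 50 of them by older names, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, for lists of at least 5 tested members and adjusted over the lists of a comparison. camera with an estimated correlation and fry, which asks whether a list's genes move one way and does not compare them with other genes, were alternatives. Of the lists called with the preset correlation in the 8 comparisons (17 and 14 in HepG2 under AA and AL, 16 between AA and AL, then 7, 13 and 15 in LX2, and 11 and 11 for the differences between lines), 3, 0, 0, 0, 0, 0, 4 and 1 were called with an estimated correlation too.

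The comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. Per comparison with DMSO, the rule took the 8 genes of largest rise and the 8 of largest fall among called genes with a mean of at least 2 CPM in the higher group. Their libraries in the 2 groups could not overlap, and clone-based, LOC, LINC, antisense, MIR and SNOR names were left out. Between compounds and between lines it took 5 per direction, between lines with overlap allowed. It added up to 4 members of each list by adjusted p, and always CYP1A1, CDKN1A, MDM2, GDF15, HMOX1, NQO1, ALB, COL1A1 and ACTA2. The text names those of them that fit its space, and some genes are not reported here. The alternatives were RLE scaling, DESeq2 1.42.0, no low count filter, a filter of 1 CPM in 3 libraries, the sample number as a replicate block, robust=FALSE, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 0.5 and on log2(FPKM + 1) without that filter, only the 6 libraries compared, all 18 libraries, and each library left out in turn. Offsets that remove each library's trend on gene length were added after the data were seen, as was leaving out AA and AL libraries for the genes called with both compounds. Overlaps between AA and AL were set beside 20 simulations of unchanged groups against the same DMSO libraries. The genome reference at hand was GRCh38 with GENCODE 29, another build than the authors'. It therefore gave only gene names, span, GC content, biotype and neighbours, and no coordinates are printed. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

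The tests were tried on simulated counts with 200 changed genes. For HepG2 AA against DMSO (13883 genes), edgeR recovered 32% of genes changed 1.2-fold, 88% at 1.5-fold, 94% at 2-fold and 100% at 4-fold, with 8 calls among unchanged genes. For LX2 under AA (15403) it recovered 44%, 86%, 96% and 98%, with 14 such calls. For the interaction under AA (16744) it recovered 14.3%, 72.7%, 81.4% and 89.8%, with 25. With no gene changed (HepG2 AL against DMSO), edgeR, DESeq2 and limma on log2(FPKM + 1) each called 0 genes. A raised list of 30 members in HepG2 had a camera adjusted p of 3.03e-31 (0.00206 with an estimated correlation). Of 20 unchanged lists, camera and fry called 0. Another split of the real libraries gave 236 genes, so these rates may not hold there.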

Results

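The series measured the transcriptomes of 2 human liver lines after exposure to aristolochic acid I, a nitrophenanthrene carboxylic acid of Aristolochia plants, and to aristolactam AII, a related phenanthrene lactam. HepG2 is a hepatoblastoma-derived line used as a model of hepatocytes, and LX2 is a line of activated hepatic stellate cells, the cells that deposit matrix in the fibrotic liver. A single line stands for each cell type, so a difference between the lines may not be one between cell types. The p53 protein was not measured, so a missing rise of its targets does not show that DNA damage was absent. Cells in 12 well plates received 30 µM of a compound, or the solvent DMSO, for 48 h, and each of the 6 groups had 3 libraries (18 in all). The series sets out to evaluate the liver toxicity of the compounds. Total counts per library ran from 37697210 to 41142451, which puts a library's floor of 3 counts at 0.0729 to 0.0796 CPM. The labels abbreviate aristolochic acid I as AA, and the libraries coded AA are called AA below. The code AAA is spelled out in no label and was taken as aristolactam AII (AL below) because no other group remained. It could also abbreviate another name of the acid, in which case the compound names swap and the values stay. The replicates are not said to be separate cultures, so p-values measure the spread between these samples, which may be technical. Values are log2 fold changes ± SE or mean CPM ± SD with n = 3 per group. Strand use in counting was not stated, so genes that overlap an annotated neighbour are uncertain to that extent. Among those named below these are ACTA2, FAS, CDKN1A, MDM2, TP53I3, IER3, BHLHE40, FAM83E, EPHX1, GPX2, SQSTM1, TGFB1, VIM, MICOS13, PYCARD, ENO1, COL5A1, SPDYA, PGK1, MAPT, PLAU, SAMD11, BACE2, SULF2 and ITIH4. Ribosomal protein, histone, UGT2B, CYP4F, CYP2C and AKR1B genes have near-identical copies and are uncertain for that reason.

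In HepG2, targets of p53, the transcription factor activated by DNA damage, rose together under AA. CDKN1A, the cell cycle inhibitor p21, went from 65.5 ± 1.44 CPM in DMSO to 593 ± 4.89 CPM (3.18 ± 0.05, edgeR adjusted p = 1.76e-34). MDM2, the ubiquitin ligase of p53, rose from 131 ± 7.97 to 366 ± 17.1 CPM (1.48 ± 0.05), the oxidoreductase gene TP53I3 by 3.72 ± 0.06, the ferredoxin reductase gene FDXR by 2.96 ± 0.05 and the secreted stress factor GDF15 by 1.05 ± 0.07. Of the 32 tested p53 targets, 30 were higher, none lower and 2 did not pass, with 30 also when adjusted over the list alone (median 1.96; camera adjusted p = 6.54e-14, and adjusted p = 0.0351 with an estimated correlation). Apoptosis regulators were higher for 20 of 26 and lower for 1, the same counts adjusted over the list alone, and 5 did not pass (median 0.76; camera adjusted p = 5.54e-05, adjusted p = 0.0351 with an estimated correlation). Among them the BH3-only gene PMAIP1 rose by 3.74 ± 0.22, the pore former BAK1 by 1.36 ± 0.08 and the death receptor FAS from 7.47 to 46.3 CPM (2.63 ± 0.10).

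Genes of G2/M and mitosis fell under AA in HepG2: 31 of 40 were lower (32 adjusted over the list alone), 1 was higher and 8 did not pass (median −0.41; camera adjusted p = 4.04e-06, lost at adjusted p = 0.116 with an estimated correlation). The topoisomerase TOP2A changed by −0.70 ± 0.04, and the mitotic kinases AURKA and PLK1 by −0.71 ± 0.05 and −0.68 ± 0.05. G1/S and DNA replication genes went both ways, with 12 higher and 19 lower of 40 also when adjusted over the list alone (camera adjusted p = 0.190). Excision and crosslink repair genes did so too, with 14 higher and 9 lower of 33 (14 and 9 adjusted over the list alone; camera adjusted p = 0.661). Replication-dependent histone genes were higher for 9 of 10 and lower for 1, as when adjusted over the list alone (median 1.82; camera adjusted p = 0.0104, adjusted p = 0.151 with an estimated correlation). H2BC12 rose by 1.59 ± 0.12 and H1-2 by 1.71 ± 0.14.

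Drug-metabolizing enzymes and transporters were higher for 26 of 34 and lower for 5 in AA-treated HepG2, also when adjusted over the list alone (median 0.86; camera adjusted p = 0.000138, adjusted p = 0.0351 with an estimated correlation). The glucuronosyltransferase UGT2B7 rose from 9.71 to 89.2 CPM (3.20 ± 0.08), the fatty acid hydroxylase CYP4F2 by 3.09 ± 0.12, the carboxylesterase CES2 by 1.62 ± 0.05 and the epoxide hydrolase EPHX1 by 1.44 ± 0.05. CYP1A1, the classic target of the aryl hydrocarbon receptor AHR, rose from 5.27 ± 1.23 to 37.95 ± 4.65 CPM (2.85 ± 0.13, adjusted p = 3.93e-16). The 8 tested AHR targets were higher for 4 and lower for 2, also adjusted over the list alone (camera adjusted p = 0.409). NRF2 targets of the oxidative stress response were higher for 19 of 27 and lower for 2, as adjusted over the list alone (median 0.33; camera adjusted p = 0.00204, adjusted p = 0.420 with an estimated correlation). The aldo-keto reductase AKR1B10 rose by 2.83 ± 0.05 and the glutathione peroxidase GPX2 by 1.23 ± 0.04, against 0.26 ± 0.04 for the quinone reductase NQO1 and 0.31 ± 0.07 for the heme oxygenase HMOX1.

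Lists of secreted hepatocyte proteins, acute phase genes, cholesterol synthesis and sugar metabolism had camera calls downward in the same cells, each lost with an estimated correlation. Secreted hepatocyte proteins were lower for 29 of 45 and higher for 7, also adjusted over the list alone (median −0.32; camera adjusted p = 0.00159, adjusted p = 0.447 with an estimated correlation). Ceruloplasmin (CP) changed by −1.09 ± 0.05, prothrombin (F2) by −0.84 ± 0.04 and apolipoprotein B (APOB) by −1.13 ± 0.05, although the APOB call was lost when all 18 libraries shared a fit (adjusted p = 0.0945; 7.11e-178 to 0.0945 over its alternatives). Albumin (ALB) did not pass, with −0.02 ± 0.04 (95% interval −0.10 to 0.07; adjusted p = 0.723) and 0.13 on the FPKM scale. A summed share of 10 hepatocyte transcripts, as a percent of the HepG2 mean, stood at 82.9 ± 0.224 in AA, 109 ± 3.29 in AL and 108 ± 2.87 in DMSO. Acute phase genes were lower for 10 of 15 and higher for 2, as adjusted over the list alone (camera adjusted p = 0.00767, adjusted p = 0.356 with an estimated correlation). The iron hormone hepcidin (HAMP) went from 52.6 to 7.92 CPM (−2.73 ± 0.08). The change was −2.54 ± 0.12 for the cytokine signalling inhibitor SOCS3 and −1.96 ± 0.09 for the transcription factor CEBPD. Cholesterol synthesis genes were lower for 19 of 24 and higher for 1, also adjusted over the list alone (median −0.67; camera adjusted p = 5.54e-05, adjusted p = 0.356 with an estimated correlation). The synthesis enzyme SQLE changed by −1.36 ± 0.06.

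Glycolysis and hypoxia genes were lower for 23 of 30 and higher for 5 under AA, as adjusted over the list alone (median −0.55; camera adjusted p = 0.000262, adjusted p = 0.534 with an estimated correlation). The glucose transporter SLC2A1 changed by −1.40 ± 0.05, the collagen prolyl hydroxylase P4HA1 by −1.19 ± 0.05 and the glycolytic enzyme PGK1 by −0.97 ± 0.05. Of 11 gluconeogenesis and glycogen genes, 8 were lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.0107, adjusted p = 0.213 with an estimated correlation). It was −1.14 ± 0.07 for the glucose-6-phosphatase G6PC1 and −0.68 ± 0.04 for PCK2. Cytosolic ribosomal protein genes were lower for 67 of 73 and higher for 3, as adjusted over the list alone (median −0.31; camera adjusted p = 2.68e-10, adjusted p = 0.488 with an estimated correlation). RPL12 changed by −0.70 ± 0.04 and RPL3 by −0.68 ± 0.04. ER chaperone genes were lower for 13 of 22 (14 adjusted over the list alone) and higher for 3. HSPA5 and PDIA4 both changed by −0.66 ± 0.04. Their camera adjusted p was 0.0299, with adjusted p = 0.488 with an estimated correlation, 0.0555 with 1 CPM in 3 libraries and 0.0511 without the AA library 1 (9.26e-05 to 0.488 over all alternatives).

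Heat shock genes moved up in AA-treated HepG2, with 14 of 18 higher and 2 lower, also adjusted over the list alone (median 0.83; camera adjusted p = 0.000666, adjusted p = 0.199 with an estimated correlation). The chaperones HSPH1, HSPA4L and HSP90AA1 rose by 1.45 ± 0.06, 1.79 ± 0.07 and 0.80 ± 0.04. Interferon-stimulated genes were higher for 15 of 23 and lower for 2, as adjusted over the list alone (camera adjusted p = 0.00767, adjusted p = 0.116 with an estimated correlation). ISG15 rose by 1.62 ± 0.08 and IFI6 by 1.16 ± 0.09, and IFI35 changed by −2.22 ± 0.14. Matrix proteases and inhibitors were higher for 10 of 17 and lower for 2, also adjusted over the list alone (camera adjusted p = 0.00767, adjusted p = 0.213 with an estimated correlation). Urokinase (PLAU) rose by 3.67 ± 0.29, the protease MMP14 by 1.64 ± 0.07 and the inhibitor TIMP1 by 1.52 ± 0.06. Lysosome and autophagy genes were higher for 18 of 31 and lower for 7, as adjusted over the list alone (camera adjusted p = 0.0291, adjusted p = 0.447 with an estimated correlation, and 0.0515 without the DMSO library 1; 2.19e-05 to 0.447 over all alternatives). The autophagy receptor SQSTM1 rose by 1.31 ± 0.04 and MAP1LC3B by 1.07 ± 0.05. Of the 28 ATF4 and amino acid response genes, 11 were higher and 11 lower, also adjusted over the list alone, with a median of −0.04 and a mean of 0.27 (camera adjusted p = 0.977). The fibroblast genes COL1A1 and ACTA2, a collagen and an actin, rose by 2.02 ± 0.32 (0.960 to 3.90 CPM) and 2.30 ± 0.05 (66.0 to 325 CPM). Their lists were not called. Collagens and matrix genes were higher for 9 of 32 and lower for 12, also adjusted over the list alone, with a median of 0.16, a mean of 0.28 and a negative camera direction (camera adjusted p = 0.885). Contractile and cytoskeletal markers of stellate activation were higher for 15 of 23 and lower for 5, as adjusted over the list alone (camera adjusted p = 0.0852).

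The largest changes in HepG2 under AA came from genes at the floor in DMSO. WFIKKN2 had 0 counts in DMSO and 13.4 CPM in AA, at least 523-fold higher against a floor of 3 counts, and FAM83E at least 203-fold by the same bound. GRIN2C, a glutamate receptor subunit gene, had 1 count in DMSO and 3526 in AA, a ratio of 3347 (95% counting interval 600.3 to 132200). Among the lowest were ARL15 (−5.71 ± 0.36), FHIT (−5.66 ± 0.35), NBEA (−4.66 ± 0.23), PARD3B (−4.55 ± 0.13) and the tau gene MAPT (−4.00 ± 0.16). Their link to gene span was not tested. In all, 9988 of 14782 tested genes (67.6%) passed, 5093 higher and 4895 lower, of which 2017 and 1335 changed at least 2-fold. On the FPKM scale (limma, pseudocount 1) 5341 were higher and 3393 lower. The median shift per gene from the TMM scale was 0.145 log2, over the 11852 genes with values on both.

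**Figure D1:**
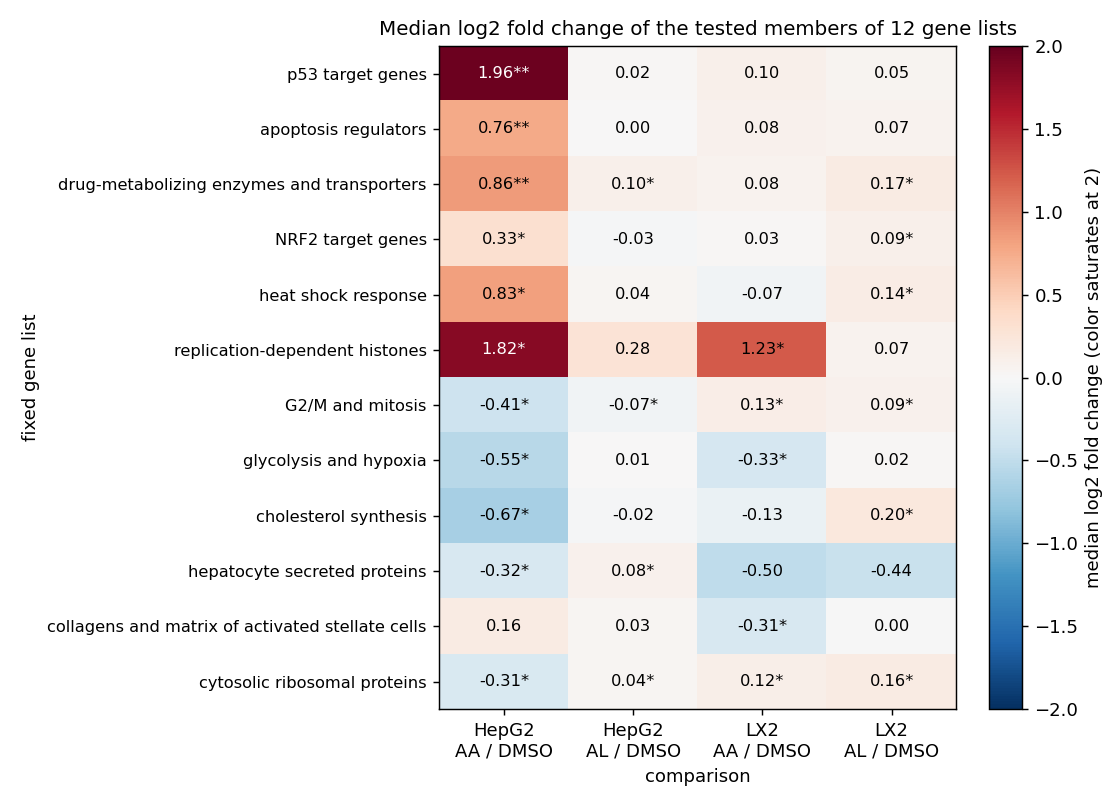
Median log2 fold change of the tested members of 12 gene lists (vertical axis) in the 4 comparisons with DMSO (horizontal axis), as color from −2 to 2 and as printed values; 1 asterisk marks a camera call with the preset correlation and 2 asterisks a call that also holds with an estimated correlation. The p53 targets stand at 1.96 in HepG2 under AA and between 0.02 and 0.10 elsewhere; the ribosomal median in HepG2 under AL, 0.04, is −0.01 with gene length offsets.

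Under AL, 29 genes passed in HepG2, and 1 other split of the same 6 libraries gave 236. On the second principal component (3.97% of variance) the AL library 1 and the DMSO libraries 1 and 2 lay at −26.4, −7.37 and −16.4, and the other 3 of these libraries at 7.50 to 28.8. The stress genes IER3 and DDIT4 fell, IER3 from 541 ± 21.6 to 346 ± 29.3 CPM (−0.65 ± 0.05, edgeR adjusted p = 5.67e-10) and DDIT4, an inhibitor of mTOR signalling, by −0.60 ± 0.06 (adjusted p = 1.17e-08). The vasodilator peptide gene ADM changed by −0.66 ± 0.10, the clock and hypoxia factor BHLHE40 by −0.38 ± 0.06 (adjusted p = 0.0673 without the DMSO library 3) and the mRNA decay factor ZFP36L1 by −0.33 ± 0.06 (0.0542 without the AL library 2). Higher genes included TRIM3 (0.86 ± 0.14), DEPP1 (0.28 ± 0.04) and the thioredoxin inhibitor TXNIP (0.33 ± 0.05; adjusted p = 0.0542 without the AL library 2 and 0.0639 without the DMSO library 1). CIDEC (0.60 ± 0.14, adjusted p = 0.0445) lost its call without any 1 library other than the AL library 2 (0.0508 to 0.18), and ESAM (0.48 ± 0.11, adjusted p = 0.0442) without any 1 other than the AL library 1 (0.0673 to 0.212). FAM3C (0.41 ± 0.09) lost it without the AA library 3 (0.0761), the AL libraries 2 (0.312) and 3 (0.126) or the DMSO libraries 1 (0.216) and 3 (0.0683). On log2(FPKM + 1) without a filter IER3 and DDIT4 kept their calls and the other genes of this paragraph lost them. With the filter DEPP1 and ZFP36L1 kept theirs too and the other 7 did not (TRIM3 at 0.41), and with only the 6 libraries compared TRIM3, CIDEC, ESAM and FAM3C lost theirs. Over all alternatives the adjusted p ran from 4.28e-05 to 0.271 for TRIM3, 1.47e-06 to 0.166 for DEPP1, 4.88e-10 to 0.371 for ADM, 2.61e-11 to 0.371 for BHLHE40, 0.000121 to 0.179 for ZFP36L1, 9.08e-08 to 0.432 for TXNIP, 0.0114 to 0.414 for CIDEC, 0.0141 to 0.365 for ESAM and 0.00397 to 0.514 for FAM3C.

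Of 13 mitochondrially encoded mRNAs, 3 were higher under AL in HepG2 (7 adjusted over the list alone) and 10 did not pass (camera adjusted p = 5.47e-06, adjusted p = 0.361 with an estimated correlation). ND1 rose by 0.38 ± 0.05, ND3 by 0.28 ± 0.05 and ND2 by 0.26 ± 0.05 (adjusted p = 0.0804 without the AL library 3 and 0.0590 without the DMSO library 2; 1.9e-07 to 0.576 over all alternatives). On log2(FPKM + 1) without a filter all 3 calls were lost (6.11e-17 to 0.271 over all alternatives for ND1). Those of ND2 and ND3 were also lost on the other FPKM scales and with gene length offsets (8.31e-08 to 0.375 over all alternatives for ND3), and that of ND2 with only the 6 libraries compared. The mitochondrial share of counts was 8.04 ± 0.740% in AL, 7.42 ± 0.347% in DMSO and 8.29 ± 0.0926% in AA. Across genes, log2 fold changes under AL in HepG2 had a Spearman correlation of −0.189 with exonic length. The median of the mitochondrial mRNAs was 0.13, or 0.08 with gene length offsets. The median of nuclear-encoded oxidative phosphorylation genes was 0.07, or 0.03 with the offsets, with 0 of 50 past the test (0 adjusted over the list alone; camera adjusted p = 8.59e-07, adjusted p = 0.301 with an estimated correlation). Secreted hepatocyte proteins had a median of 0.08, or 0.06 with the offsets, and 0 of 45 past the test (9 higher adjusted over the list alone; camera adjusted p = 1.65e-06, adjusted p = 0.301 with an estimated correlation). ER chaperones had a median of 0.09, or 0.07 with the offsets, and 0 of 22 (6 higher adjusted over the list alone; camera adjusted p = 8.16e-05, adjusted p = 0.301 with an estimated correlation). Ribosomal protein genes had a median of 0.04, or −0.01 with gene length offsets, and 0 of 73 (0 adjusted over the list alone; camera adjusted p = 0.000237, adjusted p = 0.776 with an estimated correlation, 0.101 without the AL library 3 and 0.153 without the DMSO library 1, and 1.09e-06 to 0.776 over all alternatives).

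Proliferation genes had small negative medians under AL in HepG2. The proliferation marker MKI67 changed by −0.21 ± 0.04 (adjusted p = 0.0232; 0.0524 without the AA library 2, 0.212 and 0.0618 without the AL libraries 2 and 3, 0.166 without the DMSO library 1, and 0.00243 to 0.375 over all alternatives). It was the only 1 of 40 G2/M genes past the test, with 4 lower adjusted over the list alone (median −0.07; camera adjusted p = 1.90e-05, adjusted p = 0.301 with an estimated correlation). G1/S genes had 0 of 40 (0 adjusted over the list alone; median −0.08; camera adjusted p = 1.59e-05, adjusted p = 0.301 with an estimated correlation). Of 27 immediate early genes, 1 was lower (7 adjusted over the list alone; camera adjusted p = 0.0209, adjusted p = 0.412 with an estimated correlation). Without the AL libraries 1 and 2 in turn it was 0.152 and 0.180, and without the DMSO libraries 2 and 3 it was 0.267 and 0.116 (0.000834 to 0.412 over all alternatives). Of 5 cholangiocyte markers, 1, the keratin KRT19, was higher (2 adjusted over the list alone), by 0.27 ± 0.05 (adjusted p = 0.212 without the AL library 2 and 0.248 without the DMSO library 1; 0.000136 to 0.458 over all alternatives). Its list had camera adjusted p = 0.0394 and adjusted p = 0.301 with an estimated correlation. That call was also lost with the replicate block (0.0518) and without each AA library in turn (0.0522, 0.0555, 0.0504), the AL libraries 2 and 3 (0.0932, 0.166) and the DMSO libraries 1 and 3 (0.134, 0.0665), with 0.0303 to 0.301 over all alternatives.

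None of the 32 p53 targets passed in HepG2 under AL by edgeR (2 higher adjusted over the list alone; median 0.02, mean −0.02; camera adjusted p = 0.469). CDKN1A stood at 0.01 ± 0.05 (95% interval −0.09 to 0.10) and MDM2 at −0.03 ± 0.05 (−0.14 to 0.07). Glycolysis and hypoxia genes were lower for 2 of 30, also adjusted over the list alone (median 0.01, mean −0.03; camera adjusted p = 0.767). CYP1A1 was at 7.40 CPM against 5.27 CPM in DMSO (0.49 ± 0.14, adjusted p = 0.229), which became adjusted p = 0.0128 with no low count filter and 0.00531 without the DMSO library 3 (0.00531 to 0.753 over all alternatives). ALB stood at 0.03 ± 0.04 and NQO1 at −0.01 ± 0.04. Altogether 29 genes passed, 16 higher and 13 lower, with 1247 at an unadjusted p under 0.05 and 51 by DESeq2. The split was 8 and 11 without robust variance, 2 and 3 or 0 and 2 on the FPKM scale with and without a filter, 5 and 7 with only the 6 libraries compared, and 10 and 14 with all 18. The count was 19 without the AA library 2, 65 and 12 without the AL libraries 1 and 2, and 12 and 79 without the DMSO libraries 1 and 3. More were lower than higher without the AL library 3 (9 and 12) and without the DMSO libraries 1 (5 and 7), 2 (18 and 22) and 3 (31 and 48).

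Set against each other at the same dose and time, AA and AL differed in 10093 of the 14782 genes in HepG2, 5125 higher in AA and 4968 lower (2021 and 1366 at least 2-fold). CDKN1A was 3.17 ± 0.05 higher with the acid (edgeR adjusted p = 1.9e-34), MDM2 1.52 ± 0.05, CYP1A1 2.36 ± 0.13, ACTA2 2.19 ± 0.05, COL1A1 1.78 ± 0.32 and NQO1 0.27 ± 0.04. ALB was not found to differ, with an interval of −0.13 to 0.04 (adjusted p = 0.299), but passed with opposite signs on the FPKM scale (0.12) and with gene length offsets (−0.10), with adjusted p = 0.00512 to 0.948 over all alternatives. WFIKKN2, TREM2, a microglial and macrophage receptor, UNC45B and PADI3 had 0 counts under AL and were at least 513, 487, 179 and 138-fold higher under AA. Of p53 targets 31 of 32 were higher in AA, also adjusted over the list alone (camera adjusted p = 1.02e-13, adjusted p = 0.0513 with an estimated correlation). Of apoptosis regulators 21 of 26 were higher and 1 lower, as adjusted over the list alone (camera adjusted p = 0.000102, adjusted p = 0.0513 with an estimated correlation). Drug-metabolizing genes were higher for 23 of 34 and lower for 5 (24 and 6 adjusted over the list alone; camera adjusted p = 0.000889, adjusted p = 0.0651 with an estimated correlation). G2/M genes were lower for 29 of 40 and higher for 2, also adjusted over the list alone (camera adjusted p = 0.000141, adjusted p = 0.197 with an estimated correlation). Cholesterol synthesis genes were lower for 19 of 24 and higher for 1, as adjusted over the list alone (camera adjusted p = 8.38e-05, adjusted p = 0.366 with an estimated correlation). Ribosomal protein genes were lower for 70 of 73 and higher for 2, also adjusted over the list alone (camera adjusted p = 1.18e-11, adjusted p = 0.445 with an estimated correlation). On the FPKM scale 5485 genes were higher and 3295 lower, with the median of all genes shifted by 0.162.

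In LX2 under AA, collagens and matrix genes were lower for 29 of 38 (30 adjusted over the list alone) and higher for 2 (median −0.31; camera adjusted p = 2.44e-08, adjusted p = 0.274 with an estimated correlation). The fibrillar collagen COL3A1 went from 190 to 89.99 CPM (−1.08 ± 0.05, edgeR adjusted p = 4.75e-17), COL1A1 from 2025 ± 29.1 to 1302 ± 52.4 CPM (−0.64 ± 0.04), COL5A1 by −0.55 ± 0.04 and the matrix glycoprotein TNC by −1.30 ± 0.05. Glycolysis and hypoxia genes were lower for 26 of 29 (27 adjusted over the list alone) and higher for none (median −0.33; camera adjusted p = 6.98e-10, adjusted p = 0.177 with an estimated correlation). Among them were BHLHE40 (−0.57 ± 0.05), the hexokinase HK2 (−0.58 ± 0.05), LDHA (−0.44 ± 0.04) and ENO1 (−0.38 ± 0.03). Contractile and cytoskeletal markers of stellate activation were lower for 15 of 26 and higher for 2, also adjusted over the list alone (camera adjusted p = 0.0285, adjusted p = 0.274 with an estimated correlation, 0.0507 without the AA library 3, 0.0549 without the DMSO library 2 and 0.000176 to 0.274 over all alternatives). The myosin light chain MYL9 changed by −0.79 ± 0.05, the cytokine TGFB1 by −0.48 ± 0.04 and vimentin (VIM) by −0.31 ± 0.04, the last with adjusted p = 0.210 when all 18 libraries shared a fit (1.95e-18 to 0.210 over its alternatives). ACTA2, smooth muscle actin, was at 0.05 ± 0.09 (interval −0.13 to 0.23, adjusted p = 0.657). Fold changes of all annotated genes under AA in LX2 had a Spearman correlation of −0.242 with the GC content of their transcripts (0.138 in HepG2). Whether this trend carries the list shifts of LX2 was not tested.

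G2/M genes of LX2 rose under AA, 26 of 40 higher (29 adjusted over the list alone) and 1 lower (median 0.13; camera adjusted p = 1.38e-05, adjusted p = 0.367 with an estimated correlation). TOP2A rose by 0.35 ± 0.04, the spindle gene HMMR by 0.41 ± 0.04 and the kinesin KIF2C by 0.35 ± 0.04. Histone genes were higher for 11 of 15 and lower for none, as adjusted over the list alone (median 1.23; camera adjusted p = 6.85e-05, adjusted p = 0.177 with an estimated correlation). H2BC12 rose by 1.23 ± 0.06 and H2BC21 by 1.65 ± 0.10. G1/S genes were lower for 16 of 40 and higher for 5, also adjusted over the list alone (camera adjusted p = 0.0420, adjusted p = 0.680 with an estimated correlation, 0.0705 without the AA library 3, 0.0746 without the DMSO library 2, 0.0534 with the replicate block, 0.0697 with 1 CPM in 3 libraries and 0.000681 to 0.680 over all alternatives). GINS4 changed by −0.78 ± 0.06 and the helicase subunit MCM5 by −0.46 ± 0.04. Ribosomal protein genes were higher for 37 of 73 and lower for 2 (38 and 4 adjusted over the list alone; median 0.12; camera adjusted p = 0.000580, adjusted p = 0.705 with an estimated correlation). The p53 targets went both ways, 10 of 31 higher (11 adjusted over the list alone) and 6 lower (camera adjusted p = 0.303). GADD45A, a DNA damage inducible gene, rose by 0.52 ± 0.05, TP53I3 went from 13.0 to 5.18 CPM (−1.33 ± 0.13), and CDKN1A and MDM2 did not pass, both with −0.08 (intervals −0.23 to 0.07 and −0.21 to 0.04). CYP1A1 rose from 5.26 to 10.5 CPM (0.99 ± 0.14), and NQO1 went from 118 to 77.6 CPM (−0.61 ± 0.05).

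The largest rises in LX2 under AA were in genes of low level in DMSO: the platelet glycoprotein gene GP5 with a ratio of counts of 286 (95% counting interval 78.9 to 2371), the growth factor gene FGF8 with 127 (34.9 to 1057), EFCAB8 (5.45 ± 0.23), the transporter SLC22A14 (5.26 ± 0.35), CYP2C19 (4.86 ± 0.70), ALPK3 (4.73 ± 0.24) and FGF18 (4.58 ± 0.53). Of 84 annotated protein-coding genes with a log2 fold change over 3, 65.5% had a same-strand gene ending within 10 kb upstream, against 23.9% of genes matched on level. Transcripts running on from such a neighbour were not tested for the genes named here. The inflammasome adaptor PYCARD changed by −3.57 ± 0.33, the mitochondrial carrier UCP2 by −3.04 ± 0.08 (63.6 to 7.74 CPM) and MICOS13 by −2.85 ± 0.12. ALDH1A1, a retinal dehydrogenase abundant in hepatocytes, went from 2.14 ± 1.08 to 0.214 CPM (−3.30 ± 0.52). The hepatocyte transcript share of LX2, as a percent of the HepG2 mean, was 0.138 ± 0.160 in DMSO, with 0.322 in the DMSO library 1, against 0.0967 ± 0.0123 in AA and 0.0988 ± 0.00879 in AL. Of 15872 tested genes 6663 passed, 3211 higher and 3452 lower, 558 and 543 at least 2-fold.

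Of 29 immediate early genes, the first genes induced by growth factors and stress, 9 were higher in LX2 under AL (13 adjusted over the list alone; camera adjusted p = 9.09e-07, adjusted p = 0.0988 with an estimated correlation). Across genes, log2 fold changes had a Spearman correlation of −0.307 with exonic length, and the AL library 3 lay at 38.9 on the second principal component, beside 6.25 and 5.95 for the other AL libraries. The transcription factor EGR1 went from 41.8 to 75.5 CPM (0.85 ± 0.06, edgeR adjusted p = 4.65e-11), ATF3 rose by 0.67 ± 0.12, MYC by 0.32 ± 0.05 and the phosphatase DUSP1 by 0.39 ± 0.08. Cholesterol synthesis genes were higher for 13 of 25 (16 adjusted over the list alone; median 0.20; camera adjusted p = 8.08e-10, adjusted p = 0.370 with an estimated correlation). INSIG1 rose by 0.34 ± 0.06 and ACAT2 by 0.31 ± 0.05. Ribosomal protein genes were higher for 53 of 73 (67 adjusted over the list alone; median 0.16; camera adjusted p = 9.51e-18, adjusted p = 0.399 with an estimated correlation). RPS26 rose by 0.27 ± 0.04 and RPL21 by 0.29 ± 0.05. That count was 28 without the AL library 3, 31 without the DMSO library 2, 10 without the DMSO library 3 and 19 with gene length offsets. Oxidative phosphorylation genes were higher for 14 of 50 (27 adjusted over the list alone; median 0.15; camera adjusted p = 3.45e-10, adjusted p = 0.399 with an estimated correlation). With gene length offsets the medians were 0.11 for immediate early genes (0.17 without), 0.15 for cholesterol synthesis, 0.06 for ribosomal protein genes and 0.06 for oxidative phosphorylation.

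G2/M genes in LX2 under AL were higher for 13 of 40 and lower for 2 (20 and 3 adjusted over the list alone; camera adjusted p = 5.65e-06, adjusted p = 0.370 with an estimated correlation). Heat shock genes were higher for 9 of 18 (12 adjusted over the list alone; camera adjusted p = 1.03e-05, adjusted p = 0.399 with an estimated correlation). Genes of senescence-associated secretion were higher for 9 of 18 (10 adjusted over the list alone; camera adjusted p = 7.68e-05, adjusted p = 0.370 with an estimated correlation). NF-kB targets and cytokines were higher for 8 of 33 (10 adjusted over the list alone). The chemokine CCL2 rose by 0.62 ± 0.11 and IL32 by 0.35 ± 0.06. Their camera adjusted p was 0.0312, with adjusted p = 0.399 with an estimated correlation, 0.102 and 0.0507 without the AL libraries 2 and 3, and 0.0666 and 0.0630 without the DMSO libraries 2 and 3 (0.00443 to 0.399 over all alternatives). Collagens and matrix genes were higher for 4 of 38 and lower for 1, also adjusted over the list alone (camera adjusted p = 0.790). With gene length offsets the medians were 0.08 for G2/M genes (0.09 without), 0.08 for heat shock genes (0.14), 0.12 for senescence-associated secretion (0.17) and 0.03 for NF-kB targets (0.08). COL1A1 stood at −0.01 ± 0.04 (interval −0.09 to 0.07) and 0.03 with the offsets. The p53 targets were higher for 3 of 31 and lower for 1, as adjusted over the list alone (camera adjusted p = 0.503). CDKN1A stood at 0.10 (interval −0.05 to 0.25) and MDM2 at −0.14 (−0.27 to −0.02; adjusted p = 0.128, but 0.0453 without the AL library 2 and 0.0491 without the DMSO library 1, and 0.0453 to 0.974 over all alternatives). CYP1A1 was at 0.26 ± 0.14 (interval −0.04 to 0.55).

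Single genes in LX2 under AL included the muscle growth inhibitor MSTN (1.04 ± 0.22), the natriuretic peptide NPPB (0.83 ± 0.17), the keratin KRT17 (1.07 ± 0.32, adjusted p = 0.0266, and 0.185, 0.0674 and 0.118 without the AL library 3 and the DMSO libraries 2 and 3) and the matricellular growth factor CCN2 (0.82 ± 0.13, adjusted p = 0.0618 without the AL library 3). ACTA2 rose by 0.33 ± 0.09 (adjusted p = 0.0142, and 0.139 without the DMSO library 3) and NQO1 by 0.22 ± 0.05 (adjusted p = 0.0858 without that library). ALDH1A1 changed by −2.40 ± 0.48, beside the hepatocyte transcript share of 0.322 in the DMSO library 1, CAPS by −1.34 ± 0.35 (adjusted p = 0.0518 without that DMSO library) and the hepatocyte protein gene ITIH4 by −1.14 ± 0.21. Over all alternatives the adjusted p ran from 0.0127 to 0.185 for KRT17, 3.01e-13 to 0.0787 for CCN2, 0.000465 to 0.176 for ACTA2, 7.99e-05 to 0.165 for NQO1 and 0.00296 to 0.0800 for CAPS. Altogether 1947 genes passed, 970 higher and 977 lower, and 11 and 37 of them changed at least 2-fold. The count was 1092 without the AL library 3 and 1250 and 517 without the DMSO libraries 2 and 3, and the split was 728 to 467 when all 18 libraries shared a fit. It was 1289 with gene length offsets, 1002 and 985 on log2(FPKM + 1) and log2(FPKM + 0.1), and 5 without the FPKM filter, where of the called genes in these 3 paragraphs only EGR1 kept its call.

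In LX2 the compounds differed in 7326 genes, 3589 higher in AA and 3737 lower (697 and 500 at least 2-fold). UCP2 was lower with the acid by −3.11 ± 0.08 (edgeR adjusted p = 1.2e-21), PYCARD by −3.53 ± 0.33 and MICOS13 by −2.92 ± 0.12. SLC22A14 was higher by 6.15 ± 0.38, ALPK3 by 5.58 ± 0.26, GP5 by a ratio of 575 (102.8 to 22760) and the cell cycle gene SPDYA by a ratio of 94.2 (31.9 to 459.5). Collagens and matrix genes were lower in AA for 31 of 38 (32 adjusted over the list alone; camera adjusted p = 1.41e-08, adjusted p = 0.214 with an estimated correlation). COL3A1 differed by −1.13 ± 0.05 and COL1A1 by −0.62 ± 0.04. Glycolysis and hypoxia genes were lower for 24 of 29 (25 adjusted over the list alone; camera adjusted p = 7.98e-09, adjusted p = 0.163 with an estimated correlation). Cholesterol synthesis genes were lower for 19 of 25 (20 adjusted over the list alone; camera adjusted p = 4.78e-06, adjusted p = 0.318 with an estimated correlation). INSIG1 differed by −0.79 ± 0.06. Senescence-associated genes were lower for 14 of 18, also adjusted over the list alone (camera adjusted p = 0.000639, adjusted p = 0.318 with an estimated correlation). The cytokine IL6 differed by −0.93 ± 0.10 and CXCL8 by −0.63 ± 0.05. Heat shock genes were lower for 13 of 18, as adjusted over the list alone (camera adjusted p = 0.00176, adjusted p = 0.547 with an estimated correlation). HSPB1 differed by −0.87 ± 0.04. Contractile markers were lower for 16 of 26 and higher for 3, also adjusted over the list alone (camera adjusted p = 0.00244, adjusted p = 0.163 with an estimated correlation).

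Histone genes of LX2 were higher in AA than in AL for 10 of 15, also adjusted over the list alone (camera adjusted p = 0.000300, adjusted p = 0.163 with an estimated correlation). CYP1A1 was higher with the acid by 0.74 ± 0.14, and NQO1 was lower by −0.83 ± 0.05. ACTA2 stood at −0.28 ± 0.09 (adjusted p = 0.0103, with 0.0651 without the AA library 3 and 0.0568 without the AL library 2, and 0.00116 to 0.237 over all alternatives). The p53 targets were higher for 11 of 31 and lower for 8, as adjusted over the list alone (median 0.09, mean −0.02; camera adjusted p = 0.450). CDKN1A was lower in AA by −0.18 ± 0.07 (adjusted p = 0.0445), a call lost with RLE scaling (0.0523; 0.0127 to 0.262 over its alternatives) and without the AA libraries 1 (0.200) and 3 (0.0630), the AL library 2 (0.166) or the DMSO library 1 (0.0517). MDM2 was not found to differ (interval −0.07 to 0.18; adjusted p = 0.455), and stood at −0.10 with gene length offsets.

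**Figure D2:**
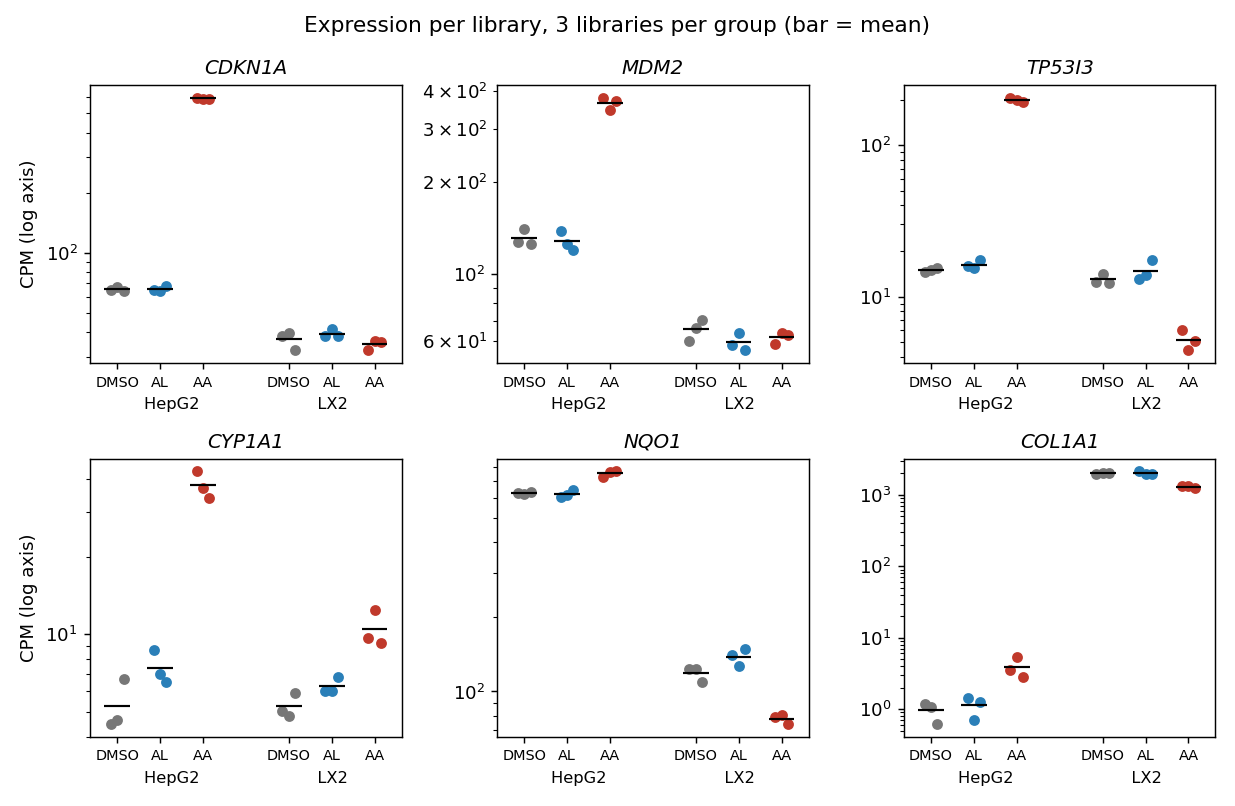
CPM per library on a log axis for CDKN1A, MDM2, TP53I3, CYP1A1, NQO1 and COL1A1, by group along the horizontal axis (HepG2 and LX2 with DMSO, AL and AA; 3 points per group, bar at the mean). CDKN1A stands at 593 CPM in HepG2 under AA against 65.5 CPM in DMSO, and COL1A1 at 1302 CPM in LX2 under AA against 2025 CPM.

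The response to AA differed between the lines in 8106 of 17544 genes by the interaction test over 18 libraries, 4146 more positive in HepG2 and 3960 more negative (5171 and 3131 on the FPKM scale, with the median of all genes shifted by 0.140). The difference was 3.24 ± 0.08 for CDKN1A (edgeR adjusted p = 8.93e-26), 5.03 ± 0.13 for TP53I3, 3.15 ± 0.09 for the p53-induced kinase PLK2 and 1.55 ± 0.08 for MDM2. For GDF15 it was 0.71 ± 0.46 (interval −0.29 to 1.71; adjusted p = 0.242). It passed for GDF15 with no low count filter (adjusted p = 0.000177) and on log2(FPKM + 1) with and without a filter (1.04), with 0.000177 to 0.9999 over all alternatives. Of p53 targets 29 of 32 responded more in HepG2 and 1 less, also adjusted over the list alone (camera adjusted p = 7.83e-18, adjusted p = 0.000670 with an estimated correlation). G2/M genes were more negative in HepG2 for 37 of 40 and more positive for 1, as adjusted over the list alone (camera adjusted p = 4.44e-13, adjusted p = 0.00758 with an estimated correlation). TOP2A differed by −1.06 ± 0.06 and PLK1 by −1.04 ± 0.07. Apoptosis regulators were more positive for 17 of 27 (18 adjusted over the list alone) and more negative for 1 (camera adjusted p = 0.000346, adjusted p = 0.00886 with an estimated correlation). Matrix proteases were so for 15 of 21 (16 adjusted over the list alone) against 1 (camera adjusted p = 0.000486, adjusted p = 0.0297 with an estimated correlation). Heat shock genes were more positive for 13 of 18 (14 adjusted over the list alone; camera adjusted p = 1.23e-05, adjusted p = 0.232 with an estimated correlation). Cholesterol synthesis genes were more negative for 19 of 25, also adjusted over the list alone (camera adjusted p = 1.93e-05, adjusted p = 0.357 with an estimated correlation). Ribosomal protein genes were so for 70 of 73, as adjusted over the list alone (camera adjusted p = 8.95e-16, adjusted p = 0.557 with an estimated correlation). COL1A1 differed by 2.64 ± 0.30, ACTA2 by 2.22 ± 0.10, CYP1A1 by 1.83 ± 0.20 and NQO1 by 0.85 ± 0.07.

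Across the 13196 genes tested in both lines, the log2 fold changes under AA had a Pearson correlation of 0.415 and a Spearman correlation of 0.287, a description across genes, which are not independent replicates. The Pearson value was 0.230 with DESeq2, 0.212 with no low count filter and 0.271 with all 18 libraries. Both lines were higher for 1568 genes, where independent lists would share 1030 (Fisher's exact p = 2.84e-118), and lower for 1429 against 1016 (p = 2.96e-71), with 724 and 703 genes called in opposite directions. Under AL the correlations were 0.0570 and 0.202, and the Pearson value ran from −0.0119 with all 18 libraries to 0.251 on log2(FPKM + 1). Higher in both lines was 1 gene, IFITM3, and lower were 3, MDN1, SRRM2 and UBR4, against 0.995 and 0.895 for independent lists (Fisher's exact p = 1 and 0.0554). The 1 became 0 with RLE scaling, on all FPKM scales, with the 6 libraries compared and with all 18, and the 3 became 0 on the FPKM scales. On leaving out a library they were 0 to 9 (0 without the HepG2 AA library 3, AL library 2 and DMSO library 1; 7 without the AL library 1; 2 and 9 without the DMSO libraries 2 and 3; 3 without the LX2 AL library 2) and 0 to 23 (6, 0 and 1 without the HepG2 AL libraries; 1, 6 and 23 without the DMSO libraries; 5 without the LX2 AL library 3). ADM, IER3 and MYBL2 were lower in HepG2 and higher in LX2. IFITM3, MDN1, SRRM2, UBR4 and MYBL2 were chosen after their values were seen.

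**Figure D3:**
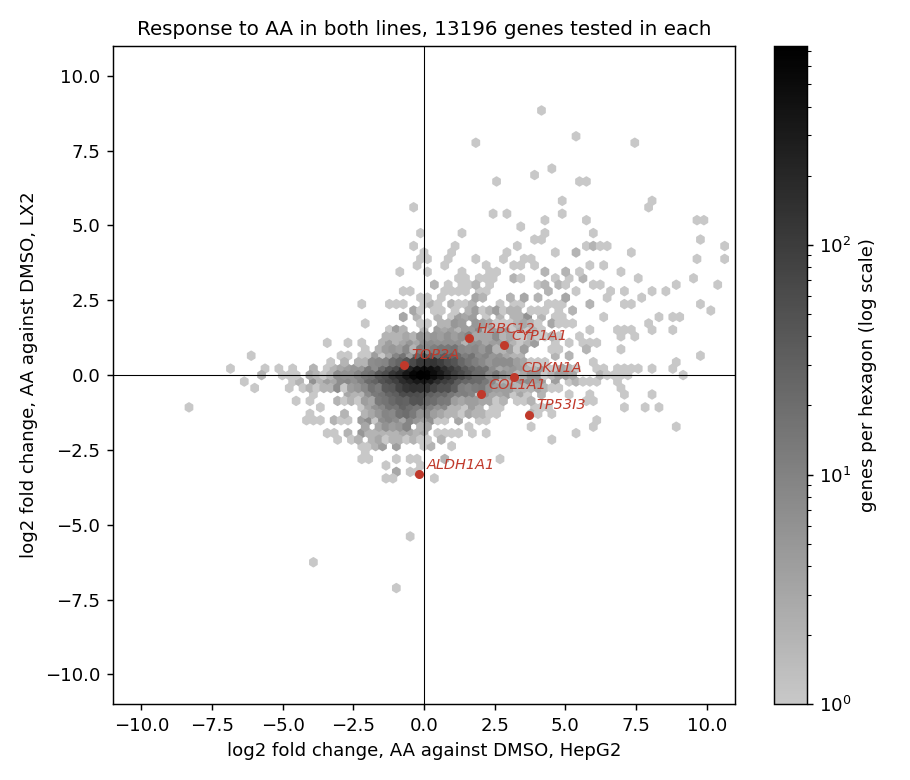
Log2 fold change of AA against DMSO in HepG2 (horizontal) and LX2 (vertical) for the 13196 genes tested in both, as hexagons shaded by the number of genes on a log scale, with 7 named genes as points. H2BC12 and CYP1A1 lie above 0 on both axes, and TP53I3 lies at 3.72 in HepG2 and −1.33 in LX2.

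The response to AL differed between the lines in 61 genes, 21 more positive in HepG2 and 40 more negative, with 2037 at an unadjusted p under 0.05 and 196 by DESeq2. EGR1 differed by −1.29 ± 0.13 (edgeR adjusted p = 3.13e-07), DUSP1 by −1.17 ± 0.18, IER3 by −0.83 ± 0.08 and DDIT4 by −0.51 ± 0.08. Immediate early genes were more negative in HepG2 for 4 of 30 (12 adjusted over the list alone; camera adjusted p = 6.40e-08, adjusted p = 0.0501 with an estimated correlation). G2/M genes were so for 4 of 40 (14 adjusted over the list alone; camera adjusted p = 7.00e-14, adjusted p = 0.0105 with an estimated correlation) and cholesterol synthesis genes for 1 of 25 (13 adjusted over the list alone; camera adjusted p = 2.86e-11, adjusted p = 0.149 with an estimated correlation). Ribosomal protein genes had 0 of 73 past the edgeR test (4 more negative adjusted over the list alone; camera adjusted p = 7.00e-14, adjusted p = 0.615 with an estimated correlation). G1/S genes had 0 of 40 (3 more negative adjusted over the list alone; camera adjusted p = 1.50e-07, adjusted p = 0.149 with an estimated correlation). Mitochondrially encoded mRNAs were more positive for 1 of 13 (8 adjusted over the list alone; camera adjusted p = 1.24e-07, adjusted p = 0.329 with an estimated correlation). The count was 36, 27 and 28 without the HepG2 AL libraries 1, 2 and 3, 34 without the HepG2 DMSO library 1, 22 without the LX2 AL library 3 and 17 without the LX2 DMSO library 3. The split was 154 to 103 without a filter on low counts and 6 to 20 or 2 to 10 on FPKM scales. It was 30 to 35 and 5 to 17 without the LX2 AL libraries 1 and 3, and 8 to 9 without the LX2 DMSO library 3.

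AA and AL share their DMSO libraries, which alone can make their calls overlap. In HepG2, 8 genes were higher and 5 lower under both (BHLHE40, DDIT4, IER3, MDN1 and ZFP36L1), where independent lists would share 5.51 and 4.30 and simulated unchanged groups 0.05 and 0.1, and 11 were called in opposite directions. In LX2, 321 were higher and 322 lower under both (196 and 212 for independent lists, 0 and 0.1 simulated), and 417 opposite. Without the DMSO library 3 these were 59 and 97, and the higher ones 209 without the AA library 1, 199 without the AL library 3, and 199 and 188 without the DMSO libraries 1 and 2. In HepG2 leaving out a library gave 3 to 19 higher (4, 4 and 5 without the AA libraries 1, 2 and 3; 15, 5 and 5 without the AL libraries; 3 and 19 without the DMSO libraries 1 and 3) and 3 to 17 lower (10 and 3 without the AL libraries 1 and 2; 11 and 17 without the DMSO libraries 2 and 3). The simulated groups had 0.2 to 0.4 called genes per direction on average, so their overlap lies near 0 and does not show what shared libraries add to lists of the observed sizes. The covariance of fold changes was 0.122 in HepG2 and 0.0424 in LX2, against 0.0282 and 0.0328 simulated (20 draws). The correlations across genes were 0.193 and 0.152, against 0.494 and 0.501. The 3 DMSO libraries cannot be split into parts of at least 2, so part of the excess may come from the shared controls. Counting intervals and floors here cover counting error only.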

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

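Sorting the splits by the treatments they kept apart was chosen after their counts were seen, and no other test in this part was chosen after its result was seen. Each result is here because an interaction test found the response to differ between HepG2 and LX2. Values of genes are log2 differences, HepG2 minus LX2.

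Under AA, 8106 genes differed. Single genes were CDKN1A (3.24), TP53I3 (5.03), PLK2 (3.15), MDM2 (1.55), NQO1 (0.85), CYP1A1 (1.83), ACTA2 (2.22), COL1A1 (2.64), TOP2A (−1.06) and PLK1 (−1.04). The camera adjusted p of the difference was 7.83e-18 for p53 targets, 4.44e-13 for G2/M genes, 0.000346 for apoptosis regulators, 0.000486 for matrix proteases, 8.95e-16 for ribosomal proteins, 1.23e-05 for heat shock genes and 1.93e-05 for cholesterol synthesis. With an estimated correlation the first 4 held (0.000670, 0.00758, 0.00886 and 0.0297), and ribosomal proteins (0.557), heat shock genes (0.232) and cholesterol synthesis (0.357) lost the call. In 1 of 40 splits of the libraries, the real one, as many genes were called. The highest other split gave 7467. It kept the treatments of HepG2 apart and mixed those of LX2, and the 37 splits that mixed them in both lines gave at most 1. Mixing treatments widens the spread, so this count tests neither chance nor whether the responses differ.

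A pair of AA results rests on groups at or near 0 counts, where the fitted value depends on the prior count. LRMDA was at −6.12 ± 2.43 (edgeR adjusted p = 0.0385), with 11.4 CPM in DMSO and 0.531 CPM in AA in HepG2, and 0 counts in DMSO and 1 count in AA in LX2. Its call was lost without the LX2 AA library 3 (adjusted p = 0.9999) and without the LX2 DMSO libraries 1, 2 and 3 (0.0570, 0.0574, 0.0574). Its adjusted p ran from 2.55e-11 to 0.9999 over all alternatives. NR3C2, the mineralocorticoid receptor, was at −6.04 ± 1.34 (adjusted p = 0.000344), with 21 counts in DMSO and 0 in AA in HepG2, and 4.87 and 4.51 CPM in LX2. On the FPKM scale without a filter it was 0.00931 (adjusted p 1.59e-05 to 0.964 over all alternatives).

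Under AL, 61 genes differed, among them EGR1 (−1.29), IER3 (−0.83), DUSP1 (−1.17) and DDIT4 (−0.51). The camera adjusted p of the difference was 7.00e-14 for G2/M genes and for ribosomal proteins, 2.86e-11 for cholesterol synthesis, 6.40e-08 for immediate early genes, 1.50e-07 for G1/S genes and 1.24e-07 for mitochondrially encoded mRNAs. With an estimated correlation G2/M genes held (0.0105), and the call was lost for ribosomal proteins (0.615), cholesterol synthesis (0.149), immediate early genes (0.0501), G1/S genes (0.149) and mitochondrially encoded mRNAs (0.329). In 4 of 40 splits as many genes were called. The highest other split gave 845 and kept the treatments apart in both lines, with those of 1 line exchanged. The next, 485 and 116, kept them apart in LX2 alone, and the 27 splits that mixed them in both lines gave at most 7. As the splits that reached 61 all hold the treatments of LX2 apart, their count does not test whether the responses differ, and by it chance is neither excluded nor supported for the count of 61. ALDH1A1 was at 2.39 ± 0.42 (adjusted p = 0.0335), with 359 and 356 CPM under AL and DMSO in HepG2 and 0.340 and 1.78 ± 0.893 CPM in LX2. The hepatocyte transcript share of the LX2 DMSO library 1 was 0.322% of the HepG2 mean. The call of ALDH1A1 was lost without the HepG2 AL libraries 1, 2 and 3 (0.0724, 0.0627, 0.0619), the HepG2 DMSO libraries 1, 2 and 3 (0.0612, 0.0555, 0.0616), the LX2 AL libraries 2 and 3 (0.0883, 0.155) or the LX2 DMSO library 2 (0.0862), with 2.11e-29 to 0.186 over all alternatives. SULF2, an extracellular sulfatase, was at −1.58 ± 0.35 (adjusted p = 0.0358), with 48.4 and 46.9 CPM in HepG2 and 0.430 and 0.138 CPM in LX2. Its call was lost without the HepG2 AL libraries 2 and 3 (0.0595, 0.0519), the LX2 AL libraries 1 and 2 (0.120, 0.111) or the LX2 DMSO libraries 2 and 3 (0.114, 0.127), with 0.00201 to 0.788 over all alternatives.

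The remaining AL genes had few counts in HepG2, and their fitted values depend on the prior count. BACE2, a membrane protease, was at 5.89 ± 1.36 (adjusted p = 0.0421) from 18 counts under AL and 0 in DMSO in HepG2 beside 30.5 and 29.2 CPM in LX2, and was −0.00151 on log2(FPKM + 1). Its call was lost with the replicate block (0.0852) and without any 1 of 8 libraries. These were the HepG2 AL libraries 1 and 3 (0.177, 0.0715), the HepG2 DMSO libraries 1, 2 and 3 (0.125, 0.103, 0.113), the LX2 AL library 3 (0.0683) and the LX2 DMSO libraries 2 and 3 (0.0601, 0.0701). SAMD11 was at 2.64 ± 0.58 (adjusted p = 0.0335) from 45 and 6 counts in HepG2 beside 8.01 and 6.80 CPM in LX2, and was −0.0256 on log2(FPKM + 1). It lost the call with the replicate block (0.0526) and without the HepG2 AL libraries 1 and 3 (0.0906, 0.0769), the HepG2 DMSO libraries 1 and 3 (0.132, 0.0508), the LX2 AL library 3 (0.0683) and the LX2 DMSO library 3 (0.0616). OAS2, an interferon-induced synthetase, was at −3.66 ± 0.82 (adjusted p = 0.0354) from 2 and 22 counts in HepG2 beside 10.9 and 8.23 CPM in LX2. It lost the call without the HepG2 AL libraries 1, 2 and 3 (0.131, 0.0904, 0.0696), the HepG2 DMSO libraries 1 and 2 (0.133, 0.0575), the LX2 AL library 3 (0.0570) and the LX2 DMSO libraries 2 and 3 (0.0501, 0.0549). Over all alternatives the adjusted p ran from 0.000956 to 1 for BACE2, 0.00371 to 0.990 for SAMD11 and 0.00219 to 0.583 for OAS2.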

How the results depend on the processing

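Gene length offsets, and leaving out AA and AL libraries for the genes called with both compounds, were chosen after the data were seen. Of 175 called gene results named in the text, 132 kept direction and call under every alternative. Over settings other than leaving out a library, 1888 of 2006 values kept both, 113 lost the call and 5 changed sign. On leaving out each library, 1551 of 1638 kept both, 87 lost the call and 0 changed sign. Calls were lost for 1 with RLE scaling, 1 with DESeq2, 1 with no low count filter, 7 with robust=FALSE, 18, 19 and 37 on the 3 FPKM scales, 11 with gene length offsets, 7 with only the 6 libraries compared and 9 with all 18 in a fit. Of 67 list calls, 59 were lost with an estimated correlation, 15 with fry, 2 with the replicate block and 2 with 1 CPM in 3 libraries (ER chaperones in HepG2, 0.0555, and G1/S genes in LX2, 0.0697, both under AA, with 9.26e-05 to 0.488 and 0.000681 to 0.680 over all alternatives). Settings gave no value in 28 cases, and DESeq2 no adjusted p in 3. Depth limits the genes near the floor of 3 counts, 0.0729 to 0.0796 CPM in a library. The cause of the changes below was not tested, unless the setting tests fewer libraries or asks for a 2-fold change.

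The count of 29 genes for HepG2 under AL became 51 with DESeq2, 75 with no low count filter, 19 with robust=FALSE, 5 and 6 on log2(FPKM + 1) and log2(FPKM + 0.1), 2 without the FPKM filter, 12 with gene length offsets, and 12 with only the 6 libraries compared. It was 12 to 79 on leaving out a library (19 without the AA library 2, 65 and 12 without the AL libraries 1 and 2, 12 and 79 without the DMSO libraries 1 and 3). The 1947 for LX2 under AL became 1002 and 985 on the FPKM scales, 5 without the FPKM filter, 1289 with gene length offsets, and 1195 with all 18 libraries. It was 517 to 2228 on leaving out a library (1092 without the AL library 3, 1250 and 517 without the DMSO libraries 2 and 3). The 61 for the difference of AL responses became 196 with DESeq2, 257 with no low count filter, 26 on log2(FPKM + 0.1), and 12 without the FPKM filter. It was 17 to 76 on leaving out a library (36, 27 and 28 without the HepG2 AL libraries 1, 2 and 3, 34 without the HepG2 DMSO library 1, 22 without the LX2 AL library 3, 17 without the LX2 DMSO library 3).

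With the sample number as a replicate block, 55 genes were called for HepG2 under AL and 40 for the difference of AL responses, and 3 and 5 genes were higher and lower under AL in both lines. With it the calls of BACE2 and SAMD11 between lines (0.0852, 0.0526), cholangiocyte markers in HepG2 under AL (0.0518) and G1/S genes in LX2 under AA (0.0534) were lost. No other named call changed, and no other count moved by over 1.5 times. The labels give no pairing, and the correlation of deviations between libraries of the same number was −0.03 to 0.04 over 18 pairs.

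Lists called with an estimated correlation numbered 3 and 0 for HepG2 under AA and AL, 0 between AA and AL, 0 in each LX2 comparison, and 4 and 1 for the differences between lines under AA and AL. With fry they were 32, 0 and 37 in HepG2, 28 for LX2 under AA, 25 for LX2 between AA and AL, and 28 and 6 for the differences between lines. Of the uncalled lists named in the text for HepG2 under AA, fry called G1/S genes (0.000809 to 0.631 over all alternatives), excision and crosslink repair (0.000516 to 0.898), AHR targets (0.000724 to 0.678), stellate activation markers (2.19e-05 to 0.447) and the ATF4 list. The ATF4 list in HepG2 under AA changed direction with fry (adjusted p = 0.0243), with RLE scaling (0.998), without the AA library 1 (0.933) and without the DMSO library 3 (0.942). It was 0.884 to 0.990 on leaving out a library. Glycolysis in HepG2 under AL did so without the AL library 1 (0.157) and the DMSO library 3 (0.522; 0.153 to 0.852), and collagens in LX2 under AL without the AL library 1 (0.797; 0.280 to 0.881).

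Genes called with AA and AL in HepG2, 8 higher and 5 lower, became 2 and 0 at 2-fold, 11 lower with DESeq2, and 3 to 19 and 3 to 17 on leaving out a library (higher 4, 4 and 5 without the AA libraries, 15, 5 and 5 without the AL libraries, 3 and 19 without the DMSO libraries 1 and 3; lower 10 and 3 without the AL libraries 1 and 2, 11 and 17 without the DMSO libraries 2 and 3). In LX2, 321 and 322 became 7 and 8 at 2-fold, and 59 to 359 and 97 to 329 on leaving out a library (higher 209 without the AA library 1, 199 without the AL library 3, 199, 188 and 59 without the DMSO libraries 1, 2 and 3; lower 97 without the DMSO library 3). Genes lower with AA in both lines became 895 without the FPKM filter. Genes higher with AL in both lines, 1, became 0 with RLE, 2 with DESeq2, 7 with no low count filter, 0 on all FPKM scales, with the 6 libraries compared and with all 18. It was 0 to 9 on leaving out a library (0 without the HepG2 AA library 3, AL library 2 and DMSO library 1; 7 without the AL library 1; 2 and 9 without the DMSO libraries 2 and 3; 3 without the LX2 AL library 2). Those lower, 3, became 7, 10, 0 and 1 with DESeq2, no low count filter, FPKM scales and the 6 libraries, in this order. It was 0 to 23 on leaving out a library (6, 0 and 1 without the HepG2 AL libraries 1, 2 and 3; 1, 6 and 23 without the DMSO libraries 1, 2 and 3; 5 without the LX2 AL library 3). The Pearson correlation of AL responses between lines, 0.0570, became −0.0119 with all 18 libraries, 0.00722 with DESeq2, 0.00420 with no low count filter, 0.124 with 1 CPM in 3 libraries, 0.105 with only the 6 libraries compared, and 0.251, 0.183 and 0.178 on the FPKM scales. It was −0.00272 to 0.0664 on leaving out a library, lowest without the HepG2 DMSO library 2, and 0.0245, 0.0365, 0.0242, 0.0373, 0.0309 and 0.0376 without the HepG2 AL libraries 2 and 3, the HepG2 DMSO library 1, the LX2 AL library 1 and the LX2 DMSO libraries 2 and 3. That of AA responses, 0.415, became 0.230 with DESeq2, 0.212 with no low count filter, 0.271 with all 18 libraries, 0.328, 0.355 and 0.288 on the FPKM scales, and 0.398 to 0.415 on leaving out a library.

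ALB changed sign on the FPKM scales in HepG2, to 0.13 against DMSO (limma adjusted p 0.00255 to 0.00740) and to 0.12 against AL (0.00512 to 0.0127). Among genes that did not pass, CDKN1A in HepG2 under AL became −0.0113, −0.0117 and −0.0113 on the FPKM scales, −0.00357 with gene length offsets and −0.0208 to 0.0240 on leaving out a library (−0.0208 without the AL library 3, −0.00720 without the DMSO library 3). MDM2 there became 0.00894 with gene length offsets and −0.0939 to 0.0178 (0.0127 without the AL library 3, 0.0178 without the DMSO library 2), and NQO1 −0.0394 to 0.00510 (the highest without the AL library 1). In LX2, ACTA2 under AA ran from −0.0627 to 0.127 (−0.00256 without the AA library 2, −0.0627 without the DMSO library 3), and COL1A1 under AL became 0.0268 with gene length offsets, 0.00268 with all 18 libraries and −0.0584 to 0.0182 (0.0182 and 0.0105 without the AL libraries 2 and 3). MDM2 between AA and AL in LX2 became −0.10 with gene length offsets. Of differences between lines, NR3C2 under AA became 0.00931 without the FPKM filter, and under AL BACE2 became −0.00151 and SAMD11 −0.0256 on log2(FPKM + 1), with and without the filter.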

Other observations

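The tests on genes near a same-strand neighbour, their limit to protein-coding genes, and the gene length offsets were chosen after the data were seen.

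Genes that span long stretches of the genome were lower in AA-treated HepG2. Among the 1357 genes of longest span (median 222 kb, 10% of the genes), 72.1% of genes were called lower and 10.9% higher, with a median of −0.69, and the correlation across genes of log2 fold change with span was −0.232 (Spearman; −0.110 with exonic length). The tables argue against few counts as the source, since the 533 genes of longest span among 5323 with at least 32 CPM had a median of −0.580. They argue against exonic length bias too, since within 5 bins of exonic length the genes of longest span stood −0.437 from the rest on average (−0.0911, −0.158, −0.441, −0.502 and −0.992 from the shortest bin to the longest). In LX2 under AA the correlation with span was 0.126, while of the 1446 genes of longest span 25.8% were called lower and 12.9% higher (median −0.05), and a response of the cells to the compound stays open and untested as a cause.

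Protein-coding genes with a log2 fold change over 3 under AA were taken, 405 in HepG2 and 84 in LX2. A same-strand gene ended within 10 kb upstream of 38% and 65.5%, against 23.8% and 23.9% of genes matched on level. This excess was not tested for chance. Over all raised genes the check was void, with 78.2% of 574 and 70.8% of 137 annotated. Reads shared with overlapping genes are argued against in both lines, since without them the excess was 15.6 and 44.9 percentage points. Gene-dense regions are argued against in LX2, where the downstream excess was 0.0463 of the upstream one, and cannot be told apart in HepG2, where 0.321 lay between the bounds set. Transcripts running on past the end of an expressed upstream neighbour may account for part of these rises: the upstream neighbours' median level was 2.93 times (33.0 against 11.3 CPM) and 2.81 times (52.5 against 18.7 CPM) that of matched genes' neighbours, and a response of the raised genes' own promoters was not tested.

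Under AL in LX2, shorter transcripts were higher: the correlation across genes of log2 fold change with exonic length was −0.307. With each library's length trend removed, the median of ribosomal protein genes was 0.0558 (0.156 before), their calls 19 (53) and all calls 1289 (1947), so length bias of RNA or library quality may account for most of the ribosomal shift. A single AL library is argued against by a small margin, since without the AL library 3, which stands apart on the second principal component (38.9; 10.3% of variance), the correlation was still −0.214, with a ribosomal median of 0.10 and 28 ribosomal calls. Without the DMSO library 3 it was −0.264, with 10 ribosomal calls and 517 calls in all (1092 without the AL library 3, 1250 without the DMSO library 2). A response of the cells to AL remains open and was not tested apart from length.

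With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 9988 genes for HepG2 under AA, 10093 for AA against AL in HepG2, and 6663, 1947 and 7326 for LX2 under AA, under AL and between them. In each of these 5 the other splits gave 0 by edgeR. They mix treatments, which widens the spread, so this does not test chance. For HepG2 under AL 2 of the 10 splits reached 29 genes, and the highest other gave 236, which points to a structure of these samples.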
